A study of Mus musculus with 2 samples.

How the data were processed

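RNA was extracted from AML12 cells at passages 14 to 16 that stably expressed H19 or carried the control virus, and sequenced on an Illumina instrument, per the labels. The labels name the RNA as polyadenylated, while the series' design text speaks of messenger RNA left after ribosomal RNA was removed. The library titled as overexpressing was taken as the H19 virus line and the one titled as control as the control virus line. There was 1 library per group, and the labels name no separate cultures.

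The submitters' processing notes name CASAVA 1.4, TopHat2 and the mouse build mm9. The program that computed expression, the use of strand and the test behind the table of differences are not given in the sources used here. The deposited values are FPKM by the authors, per the file headers, in 1 table per library and 1 table of both libraries with 21145 genes. The per-library tables held only genes above 0 and were identical to the joint table, in which the missing genes are at 0. The authors' deposited table of differences gives FPKM, a log2 ratio without a pseudocount, a p-value and a q-value, per the file headers. Its log2 ratios equal the log2 of the deposited FPKM ratios to within 1.21e-05, with a very large number in place of infinite ratios. Of the gene identifiers, 21017 were found in GENCODE mouse release M21, which is on GRCm38, and the deposited loci of 20991 of these (99.9%) overlap the GRCm38 position, so coordinates are given on GRCm38 from that annotation although the notes name mm9.

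With 1 library per group no test was run. For each gene log2(FPKM + 1) in the control library was subtracted from that in the H19 library, with a pseudocount of 1. A gene counted as at least 2-fold different when its mean FPKM over both libraries was at least 1 and its log2 difference at least 1 in size. Fixed gene lists for liver cell types, cell death, matrix, inflammation, metabolism, stress, proliferation and controls were summarised by the median over members with a mean FPKM of at least 1, called measured. Each median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and stood apart at a percentile of at most 2.5 or at least 97.5. Lists with fewer than 5 measured members were given as values. Of 35 lists, 32 were placed and 3 were not. Some lists share a few members. The named genes were H19 and Sox9, then, leaving out gene models, clones, ribosomal proteins and small RNAs, the 15 highest and 15 lowest log2 differences among genes with a mean FPKM of at least 1, then up to 4 measured members of each list with the largest difference. The rule, the lists, the comparisons and the first set of alternatives named below were fixed before the data were examined.

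The deposited FPKM hold no read totals. Depth was estimated from genes with 1 annotated transcript and over 3000 exonic bases, as the most common low value of FPKM times length; values were not whole reads, so no count model was used. FPKM of short genes rests on few reads and is unstable. Genes with close copies, overlapping genes and antisense genes share reads in ways that FPKM does not show, which concerns the glutathione transferases, Acot1, Serpina1a, C1s1, Ifit1, Airn and the mitochondrial genes among those named.

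The steps were tested on simulated data for the comparison of the H19 library with the control over 11674 genes, with noise of SD 0.374 on the log2 scale, taken from the middle of the real differences. The changed genes were drawn only from those with a control FPKM of at least 5, and the noise had the same SD at every expression level. The 2-fold rule found 7.04% of genes changed 1.5-fold, 76.4% of genes changed 2.5-fold and 100% of genes changed 4-fold, and 0.375% of unchanged genes. Changes of genes with lower expression were not simulated, so these rates do not hold for them. Of 40 simulated lists of 20 genes shifted by 0.3, 85% stood apart as higher, and of 40 lists with no shift 5% stood apart as lower and 0 as higher.

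Alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean FPKM of at least 5, 3 other scalings (median difference of 0, TPM, equal upper quartiles), thresholds of 1.5-fold and 3-fold, the per-library tables, and the mean in place of the median of a list. After the data were seen, counts over protein-coding genes, counts without genes of under 300 exonic bases, and random lists matched also on exonic length or genomic span were added. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.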

Results

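Messenger RNA was sequenced from AML12 cells, a nontumorigenic mouse hepatocyte line, after infection with a lentivirus carrying the long noncoding RNA H19 or with a control virus and selection with puromycin. There were 2 libraries, 1 per group, so no value below has a replicate error, no test was run and every difference describes these 2 libraries. The control library listed 19595 genes above 0 and the H19 overexpression library (called the H19 library) 19063. Read totals are not given in the sources used here. The lowest common step of low values, FPKM times exonic length in kilobases, was 0.042 in the control library and 0.0425 in the H19 library. This would correspond to about 23800000 and 23500000 fragments if the step is 1 fragment. The step was sought in a fixed window of low values, the same for both libraries, holding 130 control and 111 H19 library genes. That window bounded the depths that could be found, and within it they were similar. Expression is given as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), control first, and the log2 difference is that of log2(FPKM + 1), H19 library minus control, which understates differences of low genes.

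The first question was whether the library labelled as overexpressing H19 held more of that RNA. H19 (ENSMUSG00000000031, a long intergenic noncoding RNA gene on the minus strand of chromosome 7, 142575529 to 142578143, GRCm38) was listed at 0 in the control library and at 4.72 FPKM in the H19 library. None of the 18 commonly used reference genes was listed at 0 in either library, which does not test whether a weakly expressed RNA could be. The log2 difference of H19 was 2.52, a value set by the pseudocount because the control value is 0, so no fold is given. These values do not separate transcripts of the vector from those of the cell's own gene. Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760, plus strand), a transcription factor of bile duct and progenitor cells, was at 8.02 and 11.1 FPKM, a log2 difference of 0.42 and under the 2-fold rule.

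The second question was which other transcripts differed between the H19-expressing and the control cells. As a group, cell cycle genes were higher and interferon-stimulated and inflammatory genes lower in the H19 library. Of 11674 genes with a mean FPKM of at least 1, 133 were at least 2-fold higher and 183 at least 2-fold lower in the H19 library, together 2.71% of them. The median log2 difference of all these genes was 0.08, and 90 genes were higher and 232 lower by the same rule once that median was set to 0. With the upper quartiles made equal, which shifted the median by -0.11, the counts were 80 and 259. Lower genes outnumbered higher ones by the 2-fold rule under each of these scalings. They did not with a 1.5-fold threshold on the values as deposited, with their median of 0.08, which gave 1050 higher and 725 lower genes. That threshold was not combined with another scaling. Across genes, which are not independent replicates, Pearson's r between the libraries was 0.968.

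**Figure D1:**
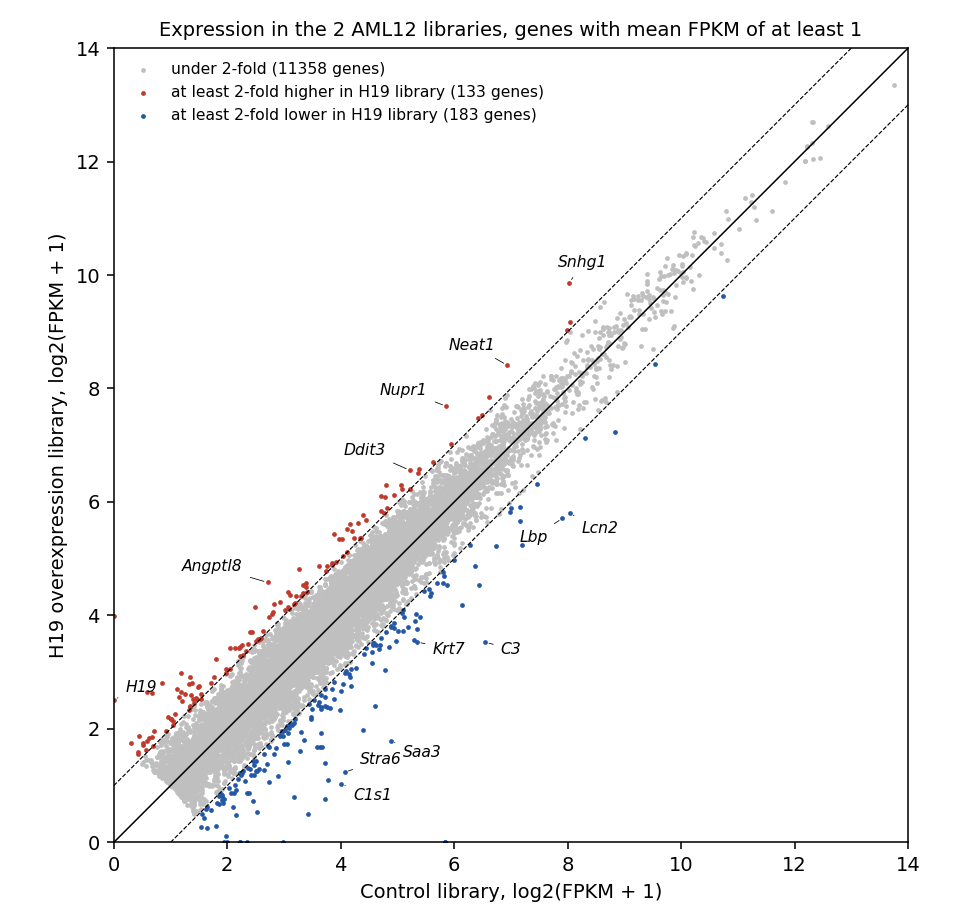
Expression of the 11674 genes with a mean FPKM of at least 1 in the control library (x axis) and the H19 library (y axis), both as log2(FPKM + 1), 1 point per gene. The solid line marks equality and the dashed lines a 2-fold difference; 133 genes lie on or above the upper dashed line and 183 on or below the lower one.

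After H19, the largest positive difference among named genes was that of Zfp758, a zinc finger gene, at 0.792 and 5.99 FPKM (log2 difference 1.96). Angptl8, a secreted regulator of lipoprotein lipase, was at 5.55 and 22.9 FPKM. Snhg1 (chromosome 19, 8723475 to 8726443), a noncoding host gene of small nucleolar RNAs, was at 260 and 930.4 FPKM (log2 difference 1.83). Nupr1, a stress-induced chromatin protein, was at 57.0 and 205 FPKM, and Neat1, the noncoding RNA that builds paraspeckles, at 121 and 339.5 FPKM. Taf1a, a subunit of the RNA polymerase I selectivity factor, was at 8.64 and 27.3 FPKM. Lgals2, a galectin, was at 26.7 and 77.6 FPKM, and Cmah, which makes N-glycolylneuraminic acid, at 16.9 and 47.8 FPKM. The remaining genes of the 15 highest were Rab26os, Pagr1a, Zfp808, Sstr2, Try5 and Dynap, with log2 differences from 1.43 to 1.79. Rab26os is an antisense gene and Try5 and the zinc finger genes have close relatives, so their values are uncertain where reads are shared.

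The lowest value was that of Saa3, an acute-phase serum amyloid, at 28.5 and 2.44 FPKM (log2 difference -3.10). C3 (chromosome 17, 57203970 to 57228136, minus strand), the central complement component, was at 92.6 and 10.6 FPKM (-3.02), and C1s1, a complement protease, at 15.1 and 1.04 FPKM (-2.98). The iron-binding acute-phase protein Lcn2 was at 262 and 54.6 FPKM, and Lbp, which binds lipopolysaccharide, at 239 and 51.4 FPKM. The immediate early transcription factors Fos (12.3 and 0.696 FPKM) and Egr1 (12.2 and 1.63 FPKM) had log2 differences of -2.97 and -2.33. Stra6, a receptor for retinol-binding protein, was at 15.8 and 1.36 FPKM, and Dhrs3, a retinaldehyde reductase, at 19.99 and 2.97 FPKM. Mt2, a metallothionein, was at 145.5 and 36.9 FPKM, and Bmf, a pro-apoptotic BH3-only protein, at 11.5 and 2.20 FPKM. Kcnj16, Ifit1 and Aldh3a1 had log2 differences of -2.20, -1.99 and -1.99. A second gene identifier of Atn1 was at 3.68 and 0.00384 FPKM while the first was at 19.1 and 18.8 FPKM, so this difference can come from how reads were divided between overlapping gene models and is uncertain.

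**Figure D2:**
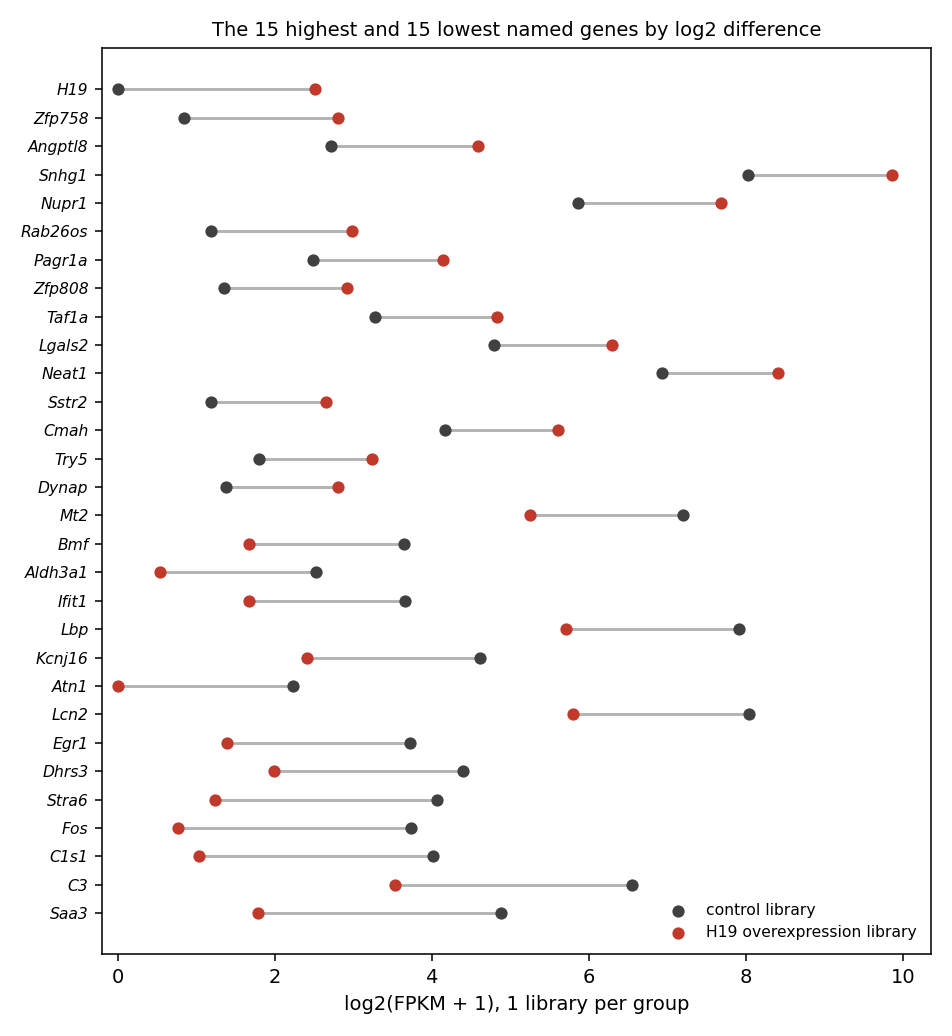
Expression as log2(FPKM + 1) of the 15 genes with the largest and the 15 with the smallest log2 difference under the naming rule, in the control library (dark points) and the H19 library (red points), 1 library per group, with lines joining the points of a gene. The differences run from 2.52 for H19 to -3.10 for Saa3.

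Interferon-stimulated and inflammatory genes were mostly lower in the H19 library. Of 36 measured interferon-stimulated genes, 33 were lower in the H19 library, 11 of them at least 2-fold. The list median was -0.74 (percentile 0 among 10000 random lists matched on mean expression). It was -0.496 with a mean FPKM of at least 5, -0.576 with no filter and -0.957 with a pseudocount of 0.1, each at percentile 0. With a mean FPKM of at least 5 the xenobiotic (-0.594) and imprinted (-0.583) lists had lower medians. Ifit1, an RNA-binding antiviral protein, was at 11.7 and 2.19 FPKM, Oasl2 at 4.22 and 0.823 FPKM, Rtp4 at 7.31 and 2.31 FPKM, and Irf7, a transcription factor that amplifies interferon production, at 3.95 and 1.12 FPKM. Of 24 cytokines, chemokines and NF-kappaB targets, 20 were lower, 7 at least 2-fold, with a median of -0.43 (percentile 0; median -0.277 with no filter). They included the adhesion molecule Vcam1 at 22.4 and 7.91 FPKM. Ptgs2, which makes prostaglandins and was named after its value was seen, went the other way at 19.9 and 53.5 FPKM. Of the macrophage and leukocyte markers, 3 were measured and all 3 were lower: Cd14, which hepatocytes also express, at 125 and 62.4 FPKM, Cd68 at 2.75 and 0.928 FPKM and Lyz2 at 1.68 and 0.412 FPKM.

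The series concerns hepatocyte death, and transcripts of cell death genes did not share a single direction. Among 22 pro-apoptotic genes 16 were lower, with a median of -0.15 (percentile 0.53; median -0.266 with equal upper quartiles). Besides Bmf these included Bnip3, a mitochondrial BH3-like protein, at 52.99 and 26.3 FPKM and Bcl2l11, which encodes Bim, at 8.72 and 4.33 FPKM, while Cycs, which encodes cytochrome c, was at 65.3 and 117 FPKM. The 13 anti-apoptotic genes had a median of -0.02 (percentile 14.9), with 1 at least 2-fold higher, Birc5, which encodes survivin and is also a mitotic gene, at 40.3 and 89.9 FPKM. The 26 p53 targets had a median of -0.02 (percentile 6.96), 13 higher and 13 lower, with Gadd45a, a growth arrest gene, at 60.3 and 129 FPKM. The 7 measured necroptosis and pyroptosis genes had a median of -0.06 (percentile 23.96), with Mlkl, the effector of necroptosis, at 14.96 and 25.3 FPKM and Il18 at 1.95 and 0.905 FPKM.

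The series also concerns liver fibrosis. Measured collagens and other matrix genes were mostly lower, 12 of 14, with a median of -0.37 (percentile 0.04, or 3.44 with no filter on low values, inside the range). The collagen genes Col1a1 (0.288 and 0.190 FPKM), Col1a2 (0.0257 and 0.0876 FPKM) and Col3a1 (0.0356 and 0.0633 FPKM) were too low to be measured. They are not among the 14. The matrix glycoprotein Thbs1 was at 4.75 and 1.404 FPKM and fibronectin, Fn1, at 93.6 and 52.4 FPKM. Of 20 TGF-beta ligands, receptors and targets 15 were lower, 3 at least 2-fold, with a median of -0.49 (percentile 0); these 3 were Id2 at 57.6 and 22.1 FPKM, Tgfb3 at 4.72 and 1.38 FPKM and the receptor Tgfbr1 at 47.1 and 20.1 FPKM. The 11 matrix metalloproteinases, inhibitors and plasminogen genes had a median of 0.05 (percentile 37.8), with a sign that turns with the median or the upper quartile set equal, with no filter (-0.026), by the mean over members (-0.0103) and, with the filter applied to TPM, under that scaling (-0.0065), and Mmp14 was at 39.2 and 19.8 FPKM. The 12 mesenchymal genes had a median of -0.15 (percentile 2.76), just inside the range of the random lists but outside it with a mean FPKM of at least 5 (-0.20, percentile 1.43) or the median of all genes set to 0 (-0.24, percentile 2.47), and at -0.275 with equal upper quartiles, although Snai2, a transcription factor of epithelial-mesenchymal transition, was at 9.44 and 21.7 FPKM. Des was the only measured stellate cell and myofibroblast marker, at 3.43 and 0.893 FPKM, and the only measured endothelial markers were Stab1 at 3.22 and 3.95 FPKM and Esam at 1.48 and 1.72 FPKM.

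Epithelial genes were lower as a group, and lists of bile duct and liver identity genes had lower medians that depended on the filter. Of 13 junction and keratin genes 12 were lower, with a median of -0.40 (percentile 0.03; median -0.238 with no filter), among them Cdh1, which encodes E-cadherin, at 44.2 and 25.6 FPKM and Cldn2 at 87.6 and 52.2 FPKM. The 10 bile duct and progenitor markers had a median of -0.39 (percentile 0.04; 3.44 with no filter on low values, inside the range), with the keratins Krt7 at 39.7 and 10.6 FPKM and Krt19 at 382 and 219 FPKM lower and Sox9 higher. Only 15 of 43 hepatocyte identity genes reached a mean FPKM of 1, with a median of -0.19 (percentile 1.43). That list lay inside the range with a pseudocount of 0.01 (percentile 2.57) or with no filter (percentile 3.55). With the filter applied to TPM its median was -0.308 (percentile 0.52). Serpina1a, an alpha-1-antitrypsin gene with close copies, was at 2.12 and 0.192 FPKM, the liver transcription factor Hnf4a at 74.4 and 44.4 FPKM, and retinol-binding protein, Rbp4, at 207 and 296 FPKM.

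Metabolic and detoxification lists were lower in most cases. The 12 xenobiotic genes had a median of -0.61 (percentile 0; median -0.203 with no filter), with the epoxide hydrolase Ephx1 at 85.9 and 22.2 FPKM. Of 21 NRF2 targets and antioxidant enzymes 18 were lower (median -0.31, percentile 0), and Gclc, which catalyses the first step of glutathione synthesis, was at 125 and 55.6 FPKM. Of 24 cholesterol synthesis and uptake genes 21 were lower (median -0.34, percentile 0), none by 2-fold, with Fdft1, the squalene synthase gene, at 16.3 and 8.59 FPKM. The 18 fatty acid oxidation genes had a median of -0.27 (percentile 0.04), with Cpt1a, which admits fatty acids to mitochondria, at 44.3 and 24.4 FPKM. The 18 fatty acid synthesis and lipid droplet genes had a median of -0.18 (percentile 0.43; median -0.309 with equal upper quartiles), although Dgat2, a triglyceride synthesis enzyme, was at 17.0 and 28.6 FPKM. The 26 glycolysis and hypoxia genes had a median of -0.23 (percentile 0; median -0.363 with equal upper quartiles), with the oxygen sensor Egln3 at 29.6 and 13.6 FPKM. The 7 bile acid genes (median -0.18, percentile 5.86) and the 12 gluconeogenesis and insulin genes (median -0.04, percentile 16.1) stayed inside the range of the random lists.

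Cell cycle genes formed the only fixed list that stood apart as higher. Of 36 measured genes 30 were higher, 2 at least 2-fold, with a median of 0.48 (percentile 100). The 6 lower genes were Ccne1, E2f1, Mcm3, Mcm6, Mcm7 and Rrm1, all of S phase entry or DNA replication. Other genes of that kind were higher, from Rrm2 (log2 difference 0.12) to Ccne2 (0.49). The centromeric histone Cenpa was at 48.5 and 104 FPKM, Cdc20, an activator of the anaphase-promoting complex, at 18.0 and 36.7 FPKM, and the mitotic kinase Aurka at 26.4 and 49.7 FPKM. The 24 endoplasmic reticulum and integrated stress response genes had a median of 0.26 (percentile 96.0), inside the range, but went both ways. The stress transcription factors Atf3 (25.03 and 68.2 FPKM) and Ddit3 (36.2 and 93.2 FPKM) and asparagine synthetase, Asns (253 and 462 FPKM), were higher, and the chaperone Pdia6 was at 62.6 and 33.3 FPKM. The 34 ribosomal protein and translation genes (median 0.20, percentile 92.4) and the 32 nuclear oxidative phosphorylation genes (median 0.15, percentile 67.5) did not stand apart.

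**Figure D3:**
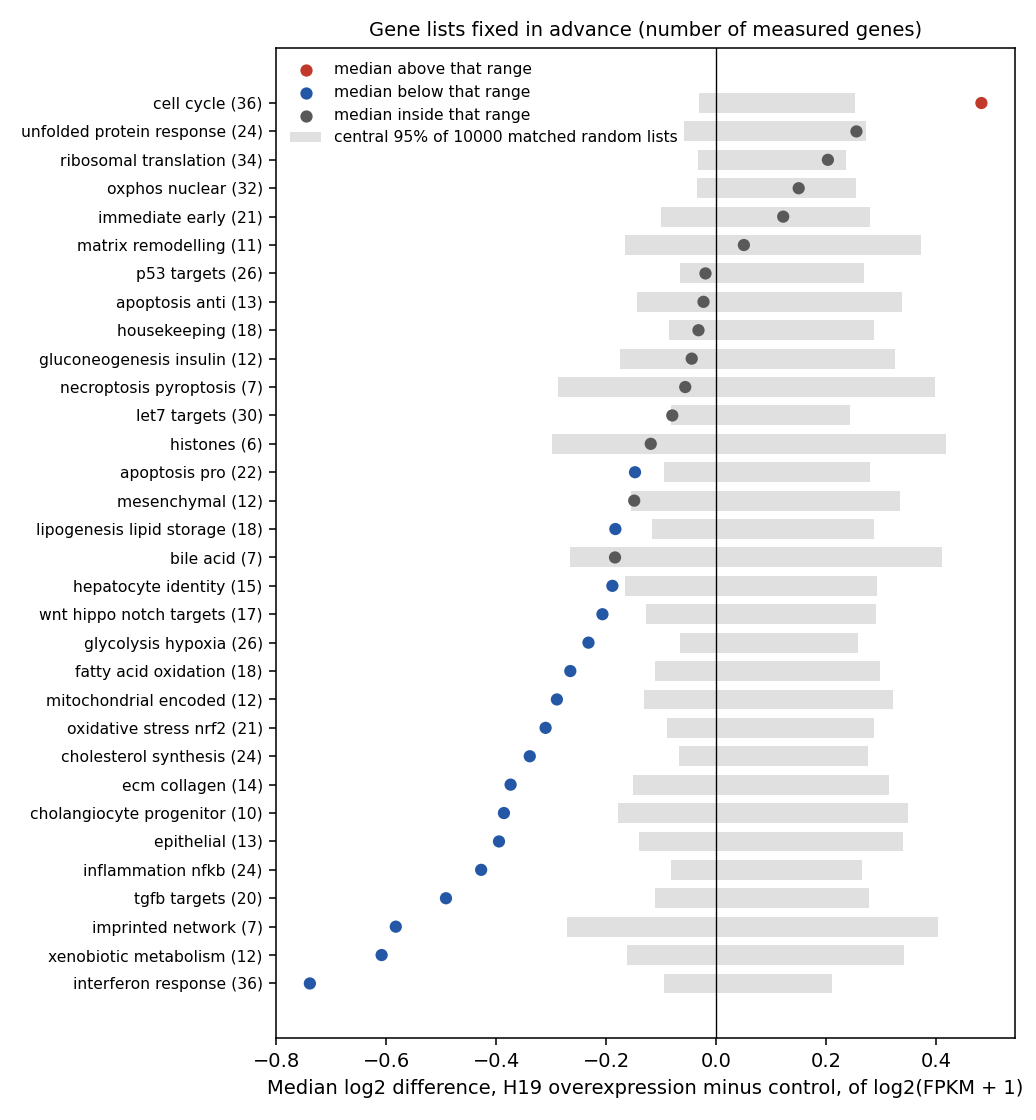
Median log2 difference of each fixed gene list with at least 5 measured genes (points; number of measured genes in brackets) beside the central 95% of 10000 random lists of the same size matched on mean expression (grey bars). Of 32 lists, 17 lie below their bar, 1 above it and 14 inside it; the interferon list is lowest at -0.74 and the cell cycle list highest at 0.48.

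Further lists covered known partners of H19 and technical controls. The 7 measured imprinted genes had a median of -0.58 (percentile 0.07), which was -0.0531 over the 27 listed genes with no filter on low values, and the members at least 2-fold lower, Cd81 (174 and 78.6 FPKM; 143052739 to 143067934) and Slc22a18 (3.39 and 1.02 FPKM; 143473736 to 143499334), lie on chromosome 7, as H19 does. The 30 targets of let-7, a microRNA family that H19 is known to bind, had a median of -0.08 (percentile 2.66), 13 higher and 17 lower, but stood apart by their mean (-0.15, percentile 0.74) and had a median of -0.194 with equal upper quartiles, with Itgb3 at 7.99 and 3.32 FPKM. The 17 Wnt, Hippo and Notch targets had a median of -0.21 (percentile 0.325; median -0.116 with no filter and -0.314 with equal upper quartiles), with Ctgf at 177 and 91.2 FPKM and Glul, a Wnt target in liver, at 76.8 and 36.8 FPKM. The 12 genes of the mitochondrial genome had a median of -0.29 (percentile 0.09), and mitochondrial genes made up 11.1% of summed FPKM in the control and 9.45% in the H19 library. The 6 measured histone genes had a median of -0.12 (percentile 14.4). It was -0.0111 with the filter applied to TPM and -0.213 with equal upper quartiles. The histone genes and the 18 reference genes (median -0.03, percentile 7.17) did not stand apart. Nor did the 21 immediate early genes, which handling can induce (median 0.12, percentile 63.4, a median that turns to -0.00365 with equal upper quartiles). Of these genes 2 were at least 2-fold higher, among them Jun at 3.79 and 10.2 FPKM, and 3 at least 2-fold lower, among them Fos and Egr1. The part of handling was not tested.

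Of the 32 lists placed, 18 stood apart, where 1.6 would be reached by chance if their genes were independent. Genes of a list vary together, so these percentiles rank a list among random genes of these 2 libraries and carry no error for the conditions. Medians near 0 move with the scaling: with equal upper quartiles those of the stress, ribosomal and oxidative phosphorylation lists were 0.128, 0.0751 and 0.0223. The mean over members was above 0 for the anti-apoptotic (0.0725), p53 (0.0542) and necroptosis and pyroptosis genes (0.102), whose medians were below 0.

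The authors' deposited table of differences between the same 2 libraries holds 561 genes, 236 higher and 325 lower in the H19 library. In the authors' deposited table the smallest finite log2 ratio was 1.00 in size and the highest q was 0.0496, and 11 ratios were infinite. It includes 286 of the 316 genes past the 2-fold rule used here and leaves out 30 of them. Of its genes, 123 had a mean FPKM under 1, and another 152 had a log2(FPKM + 1) difference under the rule. In the authors' deposited table H19 had a q of 5.22e-07, Nupr1 of 2.24e-09 and Tgfbr1 of 3.53e-05. Sox9 was not among its genes. These q-values compare 1 library with 1 library and not the conditions.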

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

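The alternatives over protein-coding genes, without short genes and with random lists matched on length or span were chosen after the data were seen. With a pseudocount of 0.1 the counts of genes at least 2-fold higher and lower were 275 and 316 and the H19 difference was 5.59, and with 0.01 they were 295 and 341 with an H19 difference of 8.89; by construction a smaller pseudocount enlarges the differences of low genes, and the 133 and 183 genes of the main rule were all among them. A mean FPKM of at least 5 left 86 and 113, from fewer genes considered. Scaling to TPM gave 346 lower genes, with values about doubled so that the pseudocount and filter weigh less, and 192 higher. Equal upper quartiles gave 80 higher genes. On the values as deposited a 1.5-fold threshold gave 1050 and 725, so that higher genes then outnumbered lower ones, and a 3-fold one 11 and 42. The other alternatives kept both counts within 1.5 times, including protein-coding genes only (95 and 162) and without short genes (127 and 174), and the per-library tables moved nothing because they hold the same values. Of the 18 lists that stood apart, hepatocyte identity no longer did with a pseudocount of 0.01 (-0.19) or no filter (-0.0514), and bile duct and progenitor markers (-0.0665) and matrix genes (-0.0347) did not without the filter. The mesenchymal list stood apart with a mean FPKM of at least 5 (-0.20) and with the median set to 0 (-0.24), and the let-7 targets by their mean (-0.15). The cause was not tested. With random lists matched on exonic length or on genomic span the same 17 lists were lower and the same 1 higher. No list or named gene past its threshold changed sign; 125 of 146 named genes other than H19 stayed on the same side of the 2-fold rule under every pseudocount and scaling. Depth is known only as an estimate, and with 1 library per group no alternative measures the spread between cultures.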

Other observations

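The 8 gene lists described first and in part below, and the genes named from them, Myc and the zinc finger genes, were chosen after the data were seen, and so were the tests of length matching for interferon genes, of leukocyte genes, of nuclear RNAs and of short transcripts. Genes of ribosome production were higher almost without exception in the H19 library. Of 51 measured, 49 were higher, 3 at least 2-fold, with a median of 0.60 (percentile 100 among matched random lists). These 3 were Taf1a, Nop14 at 97.3 and 229 FPKM and Nop56, a core protein of small nucleolar particles, at 262 and 578 FPKM. Of 23 transfer RNA synthetases and their partners 22 were higher, with a median of 0.38 (percentile 99.9) and Aimp2 at 40.8 and 94.9 FPKM. Myc, which drives ribosome production, was at 60.2 and 98.7 FPKM. Of 271 measured genes with symbols of numbered Zfp zinc finger proteins, 210 were higher and 7 at least 2-fold, 0 were 2-fold lower, so that 77.5% were higher against 58.9% of all measured genes. Their median was 0.24 (percentile 100) against 0.08 for all genes, and 0.141 against -0.03 with equal upper quartiles.

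All 15 measured genes of a complement and acute-phase list were lower, 12 of them at least 2-fold, with a median of -1.61. The list was drawn up because such genes were among the lowest, and 6 of the 15 are among the 15 lowest named genes, so its median largely restates that. The other 9 were also lower, 6 of them at least 2-fold. Of the 15, 3 are also on the inflammation list and 1 on the hepatocyte list. The copper carrier ceruloplasmin, Cp, was at 458 and 149 FPKM and complement factor B, Cfb, at 39.9 and 12.5 FPKM. Cp is among the genes of the authors' deposited table of differences and Cfb is not. Genes of antigen presentation on MHC class I had a median of -0.16 over 16 genes, at percentile 2.96. The median was -0.287 with equal upper quartiles. With random lists matched on genomic span too the percentile was 1.72 and so outside the range. Tapbp was at 33.1 and 12.3 FPKM. The 12 retinoid genes had a median of -0.04 (percentile 17.7), 6 higher and 6 lower, so the low Stra6 and Dhrs3 were not shared by the group.

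The lower interferon and NF-kappaB genes were weighed first. Random lists matched on exonic length as well as expression left the interferon median at percentile 0, which argues against a bias of expression level or transcript length as the whole cause. Leukocytes in the control culture stay open: 8 leukocyte genes summed to 1.74 FPKM there (4 of them listed above 0), which is 0.346% of the excess of Lcn2, C3, Lbp and Saa3, 0.297% of that of the lower inflammation genes without Cxcl5 and Ccl2, and 1.438% of that of the lower interferon genes without Bst2 and B2m. The fixed macrophage markers Cd68 and Lyz2 were lower in the H19 library too. They are among the 4 listed markers of that list, beyond the 8 and Cd14, that were added next. The shares then were 1.24%, 1.06% and 5.15%. These lay above the bound of 1% set against leukocytes, after the data were seen, and under the bound set for them. With the 8 genes alone the first 2 shares were under 1%, so there the outcome turned on the added markers. H19 itself cannot be told apart from any other difference between the 2 cell lines or libraries, such as clone selection or virus dose, because there was 1 library per group (value 1).

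Higher small nucleolar RNA host genes were weighed second. Of 13 host genes 12 were higher, 2 at least 2-fold, with a median of 0.41 (percentile 99.6). With length matching the percentile was 98.5 (98.52), which argues against expression level and transcript length as the whole cause. This list was drawn up after the data were seen, with the host gene Snhg1 among the 15 highest named genes. Its percentile is therefore not independent of that observation. Reduced nonsense-mediated decay predicted that the 8 decay factors, whose own mRNAs are decay targets, would be higher together. Their median was 0.48 at percentile 99.62, a test that could have come out otherwise. That test is not specific and does not decide for reduced decay, because ribosome production and transfer RNA synthetase genes lay as high. More nuclear or unspliced RNA stays open. The 6 measured nuclear noncoding RNAs other than Neat1 had a median of 0.2561 (percentile 82.6), between the bounds set for and against it. Of these RNAs 5 were higher and 1 was lower. The lower one was Airn, at 9.17 and 5.79 FPKM, while Malat1 was at 136 and 137.5 FPKM. Neat1, left out of that list, was higher at 121 and 339.5 FPKM. With equal upper quartiles the medians were 0.139 for the 6 nuclear RNAs and 0.292 for the host genes, past the bound against it. That test therefore depends on the scaling and on leaving Neat1 out. H19 as the biological difference was not testable with 1 library per group.

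The genes listed at 0 in 1 library despite a mean FPKM of at least 1 were weighed last, since H19 is among them. Of the 8 such genes, 87.5% had under 300 exonic bases, against 0.343% of all genes of known length, which is consistent with short transcripts whose FPKM is unstable. H19 was the exception, with 2460 exonic bases, so that instability does not account for its value. No biological explanation was tested for the other 7.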
